A study of Homo sapiens with 12 samples.

How the data were processed

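RNA was measured in cells of a subline of the human breast cancer line MDA-MB-231 known for its spread to bone. Per the labels, 4 groups were profiled as biological replicates on Affymetrix human gene arrays: control cells, cells with an shRNA against HMGA2 (called shHMGA2 here), and cells carrying an inducible TET1 or an inducible HOXA9 construct. Per the labels' protocols, the shRNA was delivered in a lentiviral vector with puromycin selection. The inducible lines also carried a Tet-On regulator, were selected with G418 in addition and grew in tetracycline-approved serum. Serum and selection therefore differed between these lines and control together with the construct. The source names of the TET1 and HOXA9 samples also give another subline number than their titles and cell line fields, which match control. They were treated as the same line, and another parent subline would enter every comparison of these groups with control or shHMGA2.

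The deposited table holds log2 expression values of 33297 probe sets in 12 columns, summarised by the authors with RMA in R 2.11, per the submitters' processing notes. RMA subtracts background, applies quantile normalization and summarises probes on the log2 scale. Whether all arrays were normalized together is not given in the sources used here. The control and shHMGA2 columns had a median of 7.23 and 7.26 and a lower quartile of 5.75 in both groups. The TET1 and HOXA9 columns had medians of 7.69 and 7.68 and a lower quartile of 6.24 in both groups. Such a difference among the lower values shifts fold changes between the array sets, so directions across the sets were recomputed under other scalings.

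Replicate 3 of TET1 and replicate 3 of HOXA9 equalled the mean of replicates 1 and 2 of their group in all 33297 probe sets, within a tolerance of 1e-06. These 2 columns were not counted as replicates. The comparisons therefore used 10 independent arrays (3 control, 3 shHMGA2, 2 TET1, 2 HOXA9), a departure from the plan to fit all 12 columns that was made after the data were examined. The fit on all 12 columns is given as an alternative.

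Gene names came from the platform annotation, in which 19460 probe sets have 1 gene symbol, 1754 have several and 12083 are not listed. Updating through the Entrez ID changed 0 symbols. Probe sets with 1 symbol were used, and for the 769 genes with over 1 probe set the one with the highest mean was taken, which left 18417 genes. Among named genes, FSIP2 fell by 1.82 on the log2 scale in shHMGA2, with other probe sets at -1.06 and -0.13. RNVU1-19 rose by 3.45 in TET1, with another probe set at -0.15. HLA-DPB1 rose by 0.86 in shHMGA2, with others at 0.17 and 1.23. RPL13 rose by 1.77 in TET1, with others at 0.59 and 1.39. PECAM1 fell by 0.53 in shHMGA2, with another at -0.04. HOXA9 was not analysed here, since no probe set carries its symbol alone. HMGA2 was read only from a probe set assigned to both ELAC2 and HMGA2.

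A linear model of the 4 groups was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 5.65 prior degrees of freedom). Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. No filter on dim probe sets was applied. The table has no detection calls, so a group mean below the 30th percentile of all probe sets (6.26) is not known to lie above background. A fold against such a level is that of the measured values, can understate the change in RNA, and gives no order among genes. Between the array sets it also moves with the scaling. Each changed group was compared with control, and the 3 changed groups with each other. The number of arrays limits the precision of every value.

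The gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 38 lists (pathways, gene families, markers of other cell types and small RNA classes), 36 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. Adjustment covered the 108 tests against control. The list tests of TET1 against HOXA9 were added after the data were seen and adjusted on their own. Camera with a correlation estimated per list, and fry, were run as alternatives. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

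Named genes were the 12 rising and 12 falling genes with the largest change per comparison with control, called, with groups that did not overlap and a higher group mean above the 30th percentile of all probe sets. Symbols of small nucleolar, Cajal body, microRNA and some other noncoding RNAs and of unnamed loci were left out by prefix, while other small RNAs such as VTRNA1-1, RNVU1-19 and RMRP stayed in. Up to 2 rising and 2 falling called members of each list were added. For direct contrasts and for shared responses 5 genes in each direction were taken. Genes named outside this rule are said to be so.

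On simulated data for 18417 genes with 200 changed genes, the shHMGA2 comparison recovered 50 of 50 genes changed 1.5-fold, with 11 false among 211 calls. The TET1 against HOXA9 comparison recovered 46 of 50 at 1.5-fold and 50 of 50 at 2-fold, with 10 false among 206 calls. Responses that share the control arrays were set beside 100 simulations of unchanged groups. Alternatives covered the replicate number as a block, intensity trend and robust variances, array weights, one further quantile normalization over all arrays, equal array medians, a filter on dim probe sets, the mean of a gene's probe sets, all probe sets, fits of only the compared groups, and leaving out each array in turn.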

Results

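Gene expression was measured in 4 groups of cells labelled as a bone-metastatic MDA-MB-231 subline, in 3 control arrays, 3 arrays of cells with an shRNA against HMGA2, 2 arrays labelled TET1 and 2 arrays labelled HOXA9. The source names of the TET1 and HOXA9 samples give another subline number than their titles, and they were treated as the same line. HMGA2 is a chromatin protein active in embryonic and tumour cells, TET1 oxidises 5-methylcytosine in DNA, and HOXA9 is a homeobox transcription factor. The series asks which genes each of the 3 regulates and whether they act in one pathway. Replicate 3 of TET1 and of HOXA9, as deposited, was the mean of replicates 1 and 2 and was not counted. The arrays formed 2 sets. Correlations between arrays were 0.986 to 0.998 within the control and shHMGA2 set, 0.993 to 0.997 within the TET1 and HOXA9 set, and 0.945 to 0.966 between the sets. No group had arrays in both sets, so batch, parent subline and group cannot be told apart in any comparison between the sets.

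**Figure D1:**
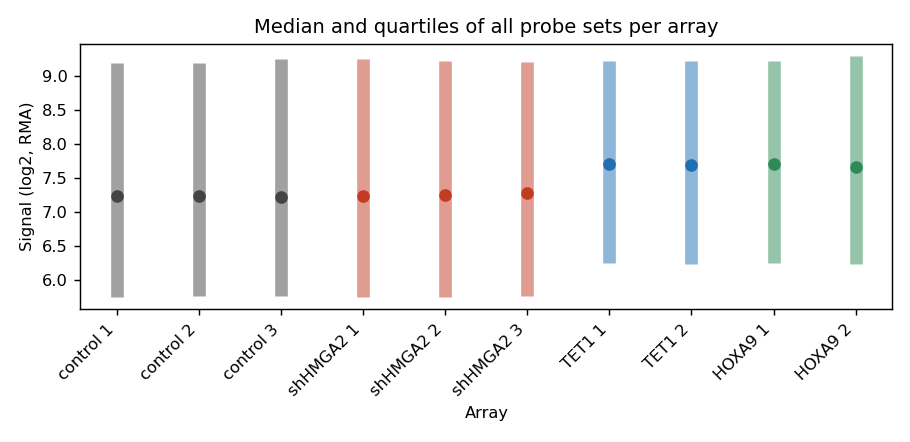
Median (point) and quartiles (bar) of the log2 expression values of all probe sets in each of the 10 independent arrays, coloured by group. Group lower quartiles were 5.75 in the control and shHMGA2 groups and 6.24 in the TET1 and HOXA9 groups, while upper quartiles lay between 9.21 and 9.26.

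The targeted genes were examined first. TET1, on chromosome 10 (probe set 7927876), rose in the shHMGA2 arrays, from 6.56 ± 0.11 in control (log2, SD, n = 3) to 8.97 ± 0.29 (n = 3). This was a 5.31-fold rise (log2 fold change 2.41, SE 0.12, 95% confidence interval 2.14 to 2.68, limma adjusted p = 1.3e-07). The SE and interval pool the spread of all 4 groups. They can be too narrow where a group varies more, as shHMGA2 did here. The probe set assigned to both ELAC2 and HMGA2 fell by 0.75 on the log2 scale (SE 0.11, limma adjusted p = 0.00053), from 9.56 ± 0.09 to 8.81 ± 0.29 (n = 3 each). A probe set of ELAC2 alone, a tRNA-processing enzyme, was at 10.72 in control and 10.86 in shHMGA2 (adjusted p = 0.15). In the same arrays 5 of 9 measured genes of the kidney cell list rose, a list of traits of the embryonic kidney line HEK293. RNA of another cell line was not excluded as a source of the TET1 rise.

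In the arrays labelled TET1, the TET1 transcript was at 7.07 ± 0.13 (n = 2), against 7.3 ± 0.14 (n = 2) in those labelled HOXA9. The difference of -0.23 between them did not pass (95% confidence interval -0.56 to 0.1, limma adjusted p = 0.69). Against control, TET1 was 0.5 higher in the arrays labelled TET1 (adjusted p = 0.0052) and 0.73 higher in those labelled HOXA9 (adjusted p = 0.00042). After one quantile normalization over all arrays these became -0.06 and 0.2, and with equal array medians 0.04 and 0.28, with no call left. The measured TET1 transcript thus does not bear out the label, and the groups are named by their labels throughout. The sample titles write Tet1, and whether the probe set sees the introduced copy is not known. The ELAC2 and HMGA2 probe set was 0.86 and 0.85 higher than control in the TET1 and HOXA9 arrays (adjusted p = 6e-05 and 7.3e-05). The probe set of ELAC2 alone was lower there (log2 -0.34 and -0.22, limma adjusted p = 0.00068 and 0.011). These comparisons cross the array sets, in which the median gene was 0.25 higher than control.

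**Figure D2:**
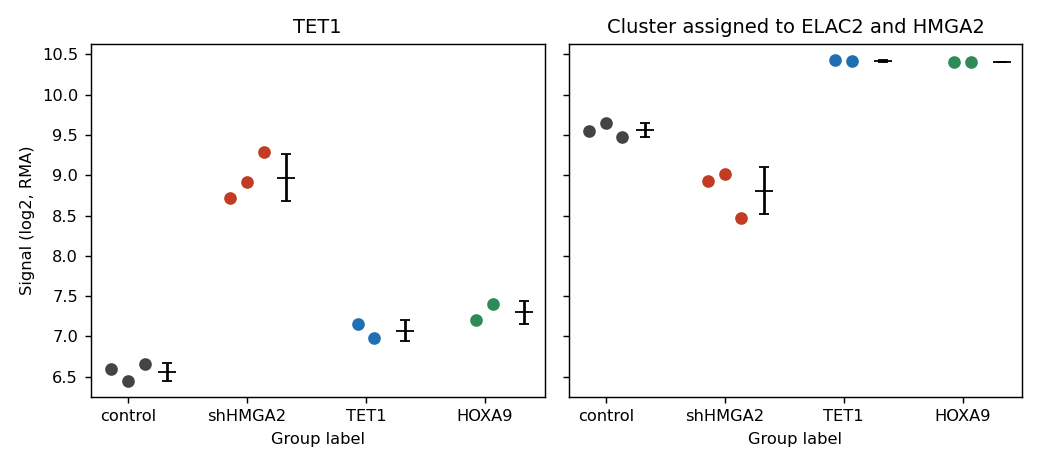
Log2 expression of TET1 (left) and of the probe set assigned to both ELAC2 and HMGA2 (right) in each array (points), with the group mean and SD beside them. TET1 was at 8.97 in shHMGA2 against 6.56 in control, and at 7.07 and 7.3 in the arrays labelled TET1 and HOXA9.

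The comparison of shHMGA2 with control asks which genes HMGA2 regulates. The largest measured rises included NETO2, an auxiliary subunit of kainate receptors (42.2-fold, from 5.62 ± 0.02 to 11.02 ± 0.28, SD, n = 3 each), IRS4, an insulin receptor substrate (35.1-fold), CA2, a carbonic anhydrase (31.9-fold), and HOXD10, a homeobox gene (22.2-fold). TLE4, a Groucho-family corepressor, rose 21.7-fold, INA, a neuronal intermediate filament, 18.6-fold, and ZCCHC12 18.4-fold. H2BC7, a histone gene, rose 16.7-fold, ID2, an inhibitor of helix-loop-helix factors, 15.4-fold, and IGF2BP1, an oncofetal RNA-binding protein, 15-fold (log2 3.91). KLHL9, a cullin adaptor, rose 13.8-fold and SLC6A15, an amino acid transporter, 11.6-fold. NETO2, IRS4, CA2, HOXD10, TLE4, H2BC7, KLHL9 and SLC6A15 lay below the 30th percentile of all probe sets (6.26) in control, where no probe set is known to be above background, so their folds can understate the change and give no ranking. CDKN2A (log2 2.48) and MTAP (log2 1.72), from a stretch that MDA-MB-231 cells are known to lack, rose in the same arrays. A gene that cells lack cannot rise by depletion of HMGA2. If the stretch is also missing in this subline, these values argue against such an effect for CDKN2A and MTAP. RNA of another cell line is therefore a candidate source of the rises and was not excluded. Which of the other rises would come from it was not settled. None of them is shown to be an effect of HMGA2. The largest falls were smaller: CYRIA, a Rac1 interactor, fell 5.51-fold (log2 -2.46, SE 0.19), AK5, an adenylate kinase, 5.15-fold, CDH11, a mesenchymal cadherin, 4.65-fold, and CCL2, a monocyte chemokine, 4.63-fold. ENTPD3, SPOCK1, MAL2, GALNT5, ABCG2, CST2 and SLAMF7 also fell (log2 -2.04, -1.87, -1.83, -1.74, -1.66, -1.55 and -1.52), as did FSIP2 in its brightest probe set (log2 -1.82). In all, limma called 4834 of 18417 genes, 2511 higher and 2323 lower, and 897 of them by at least 1.5-fold. At least 2-fold, 207 genes were higher and 65 lower.

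**Figure D3:**
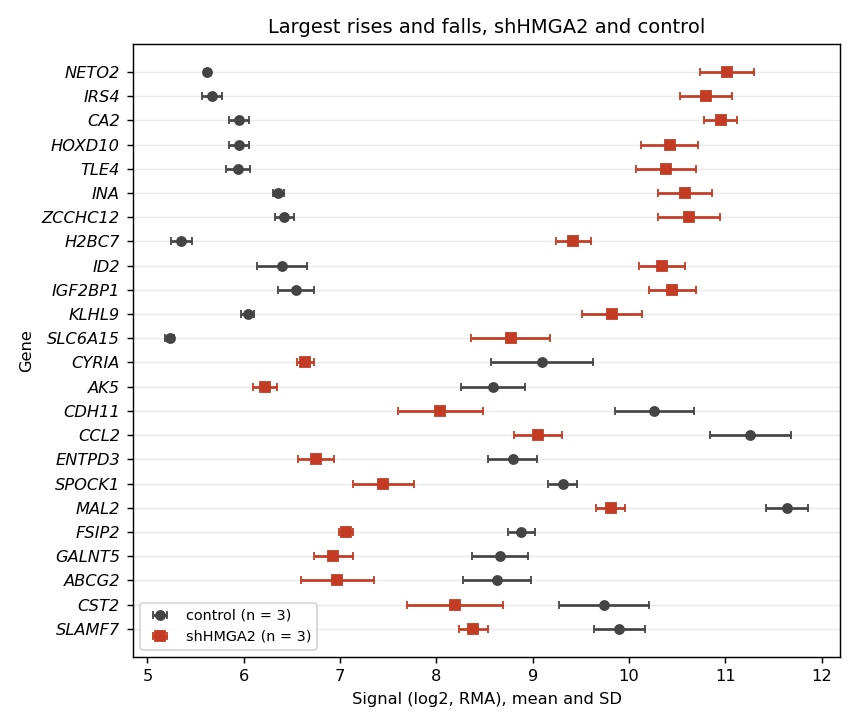
Mean log2 expression and SD (n = 3 each) of the 12 genes with the largest rise and the 12 with the largest fall in shHMGA2 (squares) against control (circles). NETO2 stood at 5.62 in control and 11.02 in shHMGA2.

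Homeobox genes outside the HOXA cluster rose: 16 of 26 measured were higher and 0 lower (18 and 0 adjusted over the list alone), led by HOXD10 and HOXD11 (3.56-fold). The list was called by camera (adjusted p = 1.9e-09), with adjusted p = 0.4 with an estimated correlation. Of the HOXA cluster, HOXA2 alone was measured, at 1.98-fold (adjusted p = 3.2e-05). Among HOXA9 partners and known leukaemia targets, 5 of 13 rose and 0 fell (5 and 0 adjusted over the list alone), with ID2 and MEIS1, a HOX cofactor (1.55-fold). Camera gave adjusted p = 0.03 for them, and adjusted p = 0.31 with an estimated correlation. Of the kidney cell list, which holds traits of the HEK293 line, 5 of 9 rose and 0 fell (5 and 0 adjusted over the list alone). These were HOXD10, the neurofilament genes NEFM (3.15-fold) and NEFL (2.25-fold), CITED1 (log2 0.54) and WT1 (log2 0.25). CDH6, LHX1, PAX2 and TFAP2B did not pass, so no kidney programme is shown. The camera test gave adjusted p = 0.0021, and adjusted p = 0.45 with an estimated correlation. HOXD10 belongs to both lists.

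On chromosome 9, CDKN2A, a cell-cycle inhibitor, rose from 7.4 to 9.88 (log2 2.48, SE 0.14, adjusted p = 3.6e-07), and MTAP, a methionine salvage enzyme, from 6.28 to 8 (log2 1.72, SE 0.1, adjusted p = 2.9e-07). KLHL9 was at 6.04 in control and 9.82 in shHMGA2. CDKN2B rose less, from 7.29 to 7.85 (adjusted p = 0.0015). In the TET1 and HOXA9 arrays MTAP stood at 6.2 and 6.24. MDA-MB-231 cells are known to lack the CDKN2A stretch, and these genes were named after some of their values had been seen.

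**Figure D4:**
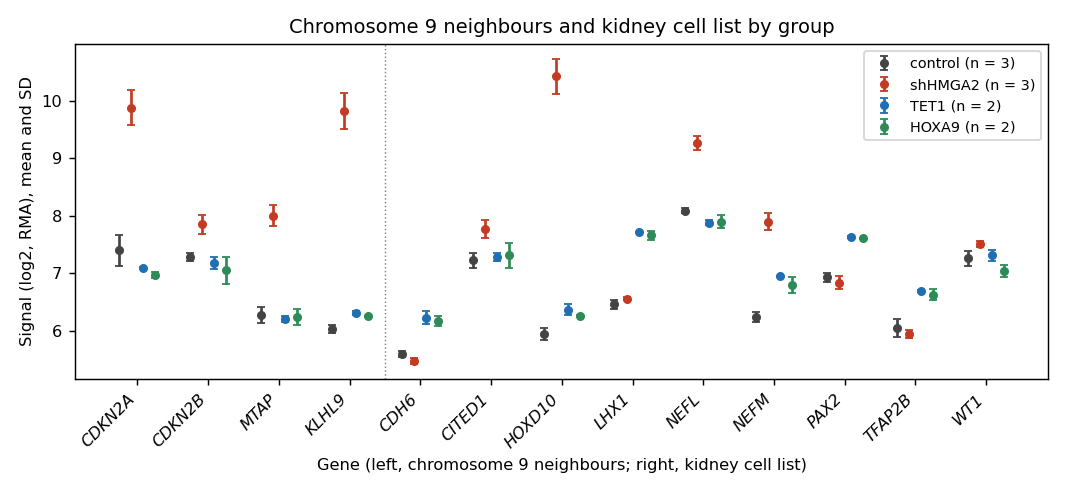
Mean log2 expression and SD in the 4 groups (n = 3, 3, 2 and 2) of 4 chromosome 9 genes (left of the dotted line) and the 9 measured genes of the kidney cell list (right). MTAP was at 6.28 in control and 8 in shHMGA2, and HOXD10 rose 22.2-fold, whereas PAX2 and LHX1 did not pass the test in shHMGA2.

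The falls below were measured in the arrays in which 5 of 9 genes of the kidney cell list, CDKN2A and MTAP rose. Dilution by RNA of another cell line was not excluded for these falls. Values given further below argue against dilution alone for falls of at least 2-fold. Interferon-response genes fell in shHMGA2: 22 of 30 were lower, with IFI44 (log2 -1.24) and SAMD9L (log2 -1.16), and 1, USP18, was higher (23 and 1 adjusted over the list alone). For this list camera gave adjusted p = 2e-07, and adjusted p = 0.31 with an estimated correlation. Of 21 genes linked to bone metastasis, 11 fell and 0 rose (13 and 0 adjusted over the list alone), with BMP4, a bone morphogenetic protein (log2 -1.45), and TNC, a matrix glycoprotein (log2 -1.16). By camera the result was adjusted p = 3e-05, and adjusted p = 0.4 with an estimated correlation. Of 23 epithelial genes 7 fell and 0 rose (7 and 0 adjusted over the list alone), with MAL2 and KRT19 (log2 -0.87). Of 14 luminal breast markers 5 fell and 0 rose (5 and 0 adjusted over the list alone), with SPDEF (log2 -1.24) and AGR2 (log2 -0.89). Camera gave adjusted p = 0.028 and 0.036 for these, and adjusted p = 0.4 with an estimated correlation for each. Of 22 matrix proteases and inhibitors 6 fell and 0 rose (9 and 0 adjusted over the list alone), with TIMP4, an inhibitor (log2 -1.09), and MMP14, a membrane protease (log2 -0.69). The camera test gave adjusted p = 0.02, and adjusted p = 0.4 with an estimated correlation.

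Ribosomal protein genes rose in part, 15 of 33 higher and 0 lower (16 and 0 adjusted over the list alone), with RPS6 (log2 0.39) and RPL7A (log2 0.34). With equal array medians 9 were higher. Of 77 H/ACA small nucleolar and Cajal body RNAs, 25 rose and 1 fell (26 and 1 adjusted over the list alone), with SNORA69 at log2 1.2. For these lists camera gave adjusted p = 8.1e-05 and 3.8e-06, and adjusted p = 0.31 with an estimated correlation for each. Of 30 DNA replication genes, 10 rose, with POLA1 (log2 0.5) and MCM6 (log2 0.49), and CCNE2 fell (10 and 2 adjusted over the list alone). By camera the result was adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation. These rises are from the arrays in which genes of the kidney cell list, CDKN2A and MTAP rose. For these rises RNA of another cell line was not excluded as the source. Of 26 hypoxia and glycolysis genes 8 fell, with VEGFA (log2 -0.68) and CA12 (log2 -0.54), and KDM3A rose (9 and 1 adjusted over the list alone). Camera gave adjusted p = 0.03, and adjusted p = 0.52 with an estimated correlation. Of 26 immediate early genes 9 fell, with DUSP6 (log2 -0.85) and DUSP4 (log2 -0.75), and 2 rose (11 and 2 adjusted over the list alone). The camera test gave adjusted p = 0.043, and adjusted p = 0.49 with an estimated correlation. Among 27 mitosis genes, HMMR rose and CDC20 fell (0 and 0 adjusted over the list alone), and camera made no call (adjusted p = 0.85). Camera called 13 of 36 lists, 0 of which were called with an estimated correlation.

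The arrays labelled TET1 and HOXA9 were compared directly within their set, which asks where the induced lines differ. MMP13, a collagenase, was 6.33-fold lower in the TET1 arrays (log2 -2.66, SE 0.09, limma adjusted p = 6.1e-08). MAL2, a membrane trafficking protein, was 6.51-fold lower, SLC14A1, a urea transporter, 6.99-fold, TMPRSS15, an intestinal protease, 4.1-fold (log2 -2.04), and RGS2, a regulator of G-protein signalling, 2.22-fold. TNFSF15, a TNF-family cytokine (2.38-fold), and KRT7, a keratin (2.02-fold), were higher, as were SERPINA3, ESM1 and EFEMP1 (log2 0.92, 0.97 and 0.9). CXCL8, a neutrophil chemokine, was higher by 0.72, and FST and TNFRSF11B, the RANKL decoy receptor, were lower (log2 -0.86 and -0.78). The microRNA list was taken by symbol and holds precursors and also host genes such as MIR600HG. Of its 189 members, 9 were lower and 0 higher (10 and 0 adjusted over the list alone), with MIR221 (log2 -1.64) and MIR181B1 (log2 -1.41). Camera made no call for it (adjusted p = 0.14). The collagen genes COL1A1 and COL1A2 were higher by 0.56 and 0.46. They were the called members both of 26 matrix genes (8 higher and 1 lower adjusted over the list alone) and of 11 fibroblast markers (4 and 0 adjusted over the list alone). For these lists camera gave adjusted p = 0.00035 and 2e-06, and adjusted p = 0.17 with an estimated correlation for each. Mitosis genes had 0 called members of 27 (0 higher and 1 lower adjusted over the list alone) and a median of -0.14, with camera adjusted p = 2e-06, and adjusted p = 0.47 with an estimated correlation. Camera called 14 of 36 lists, 0 of them with an estimated correlation.

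**Figure D5:**
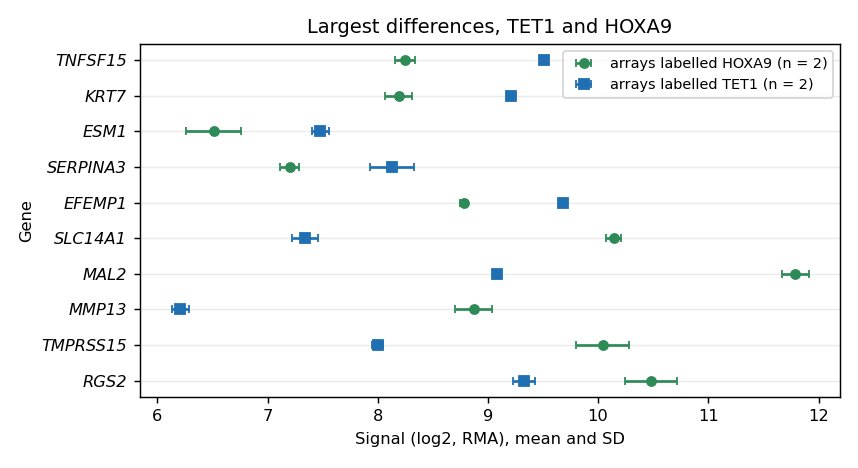
Mean log2 expression and SD (n = 2 each) of the 5 genes highest and the 5 lowest in the arrays labelled TET1 (squares) against those labelled HOXA9 (circles). The differences ran from a log2 fold change of 1.25 for TNFSF15 to -2.81 for SLC14A1.

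In all, limma called 80 genes between the arrays labelled TET1 and HOXA9, 21 higher and 59 lower in TET1. Of these, 45 differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 1686. The count was 145 after one quantile normalization (37.9% higher, against 26.2%), 142 in a fit of these groups only and 1112 with the averaged columns counted. It was 11, 18 and 17 without TET1 replicate 1, TET1 replicate 2 or HOXA9 replicate 2, and the calls of ESM1 and EFEMP1 were lost without any one of the 4 arrays. Each of these fits leaves 1 array in a compared group and takes the spread from the other groups, so a lost call there says little about the gene.

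The comparisons of TET1 and HOXA9 with control ask which genes each regulates, and both cross the array sets. COL6A3, a collagen chain, was 14.4-fold higher than control in the TET1 arrays and 11.2-fold in the HOXA9 arrays (log2 3.84 and 3.48, SE 0.08 each, limma adjusted p = 2.8e-11 and 6.4e-11). HSPA6, a stress-induced chaperone, was 12.9-fold and 11.5-fold higher, S100A4, a calcium-binding protein tied to cell motility, 8.61-fold and 9.04-fold, ANGPTL4 8.63-fold and 9.64-fold, and AGR2 7.92-fold and 14.3-fold. The small RNA VTRNA1-1, at 4.99 in control and so below the 30th percentile, was 11.5-fold and 11.7-fold higher. These folds cross array sets with unlike lower quartiles and are no lower bounds. CD96 was 8.47-fold and 11-fold higher (log2 3.08 and 3.47). PMEPA1, a TGF-beta target, ADTRP, TNFSF15 and RMRP were among the largest rises in TET1 (log2 3.43, 3.17, 3.16 and 3.08). TMPRSS15, MMP13, SLC14A1 and TGFBI were among those in HOXA9 (log2 3.68, 3.53, 3.35 and 2.97). CYP1B1, a cytochrome P450, was 8.21-fold lower in TET1 and 8.63-fold in HOXA9 (log2 -3.04 and -3.11, SE 0.5 each), as were the noncoding UCA1 (log2 -2.93 and -3.07), the collagenase MMP1 (log2 -2.86 and -2.99), P3H2 (log2 -2.84 and -2.91), CCL2 (log2 -2.79 and -2.92) and the quinone reductase NQO1 (log2 -2.59 and -2.79). TFAP2C and ZNF114 were also lower in both (log2 -2.54 and -2.46 in TET1, -2.96 and -2.59 in HOXA9). MAL2, IL7R and GMPR were among the largest falls in TET1 (log2 -2.56, -2.54 and -2.45), and SLAMF7, ROR1 and MARS2 in HOXA9 (log2 -2.35, -2.32 and -2.25).

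The median gene was 0.25 higher than control in both groups, and list medians are given relative to it. Equal array medians shift all genes of an array alike and put it at -0.22 in TET1 and -0.21 in HOXA9, so the counts under that scaling move down with it. Mitosis genes fell: 22 of 27 in TET1 and 18 of 27 in HOXA9, with 0 higher in either (24 and 18 lower adjusted over the list alone). CDC20, an activator of the anaphase-promoting complex, was at log2 -1.74 and -1.6 and AURKB, a mitotic kinase, at -1.34 and -1.42. Relative medians were -0.87 and -0.66, and camera gave adjusted p = 6.3e-10 and 7.1e-08, with adjusted p = 0.45 and 0.47 with an estimated correlation. DNA replication genes fell, 26 of 30 in TET1 and 24 of 30 in HOXA9 (26 and 24 adjusted over the list alone). CDC6, a replication licensing factor, was at log2 -1.37 and -1.32, while LIG1 rose in both (log2 0.59 and 0.6). By camera the result was adjusted p = 8.9e-11 and 6.3e-10, and adjusted p = 0.31 with an estimated correlation in each. In both lists the falls outnumbered the rises after quantile normalization. There 21 of 27 mitosis genes were lower in TET1 and 17 in HOXA9, with 0 higher. Of the 30 replication genes, 25 and 23 were lower there, with 1 higher in each group. Equal array medians gave 27 of 27 mitosis genes lower in each group, a count that their downward shift favours. Of 20 Polycomb and chromatin genes, 9 fell and 1 rose in TET1, and 10 fell and 6 rose in HOXA9 (9 and 1, and 10 and 7, adjusted over the list alone). EZH2, the H3K27 methyltransferase, was at log2 -0.94 and -0.87, and SUZ12, its partner, at -0.8 and -0.72. Camera gave adjusted p = 0.0027 and 0.024, and adjusted p = 0.34 and 0.4 with an estimated correlation. After quantile normalization camera no longer called this list, with 1 higher and 10 lower in TET1 and 3 and 11 in HOXA9. Under equal array medians 0 were higher in either group, and 19 were lower in TET1 and 17 in HOXA9.

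Hypoxia and glycolysis genes rose, 22 of 26 in TET1 and 20 of 26 in HOXA9, with ADM lower in both (22 and 20 higher, 1 lower in each, adjusted over the list alone). NDRG1 was 4.67-fold and 4.51-fold higher, and PFKFB4, a glycolytic regulator, 3.16-fold and 3.69-fold. The camera test gave adjusted p = 0.0038 and 0.0032, and adjusted p = 0.45 with an estimated correlation in each. Quantile normalization over all arrays left 18 higher and 1 lower in TET1, and 19 and 0 in HOXA9. With equal array medians 15 rose and 6 fell in TET1, and 14 and 7 in HOXA9. Matrix genes rose, 20 of 26 with 2 lower in TET1 and 19 with 3 lower in HOXA9 (20 and 3, and 19 and 3, adjusted over the list alone), with COL6A3 and with COL1A2 at log2 1.79 in TET1 and TNC at 1.56 in HOXA9. For this list camera gave adjusted p = 0.02 and 0.049, and adjusted p = 0.4 and 0.45 with an estimated correlation. Under quantile normalization 20 matrix genes rose and 3 fell in TET1, and 16 and 4 in HOXA9. With equal array medians 13 rose and 5 fell in TET1, and 13 and 6 in HOXA9. Of 77 H/ACA small nucleolar and Cajal body RNAs, 65 rose in each group, with 6 lower in TET1 and 4 in HOXA9, and the counts were the same adjusted over the list alone. SNORA60 was 17.6-fold and 17.4-fold higher. By camera the result was adjusted p = 2.7e-07 and 4e-07, and adjusted p = 0.31 with an estimated correlation in each. Quantile normalization gave 56 higher in TET1 and 51 in HOXA9, with 9 lower in each. With equal array medians 48 rose in each group, with 13 lower in TET1 and 12 in HOXA9. Ribosomal protein genes rose, 24 of 33 with 3 lower in each group (24 and 3 adjusted over the list alone), with RPL27 at 3.11-fold and 3.01-fold. Camera gave adjusted p = 0.023 and 0.036, and adjusted p = 0.45 with an estimated correlation in each. Under quantile normalization 22 rose and 6 fell in TET1, and 20 and 5 in HOXA9. Under equal array medians 13 rose and 10 fell in TET1, and 12 and 10 in HOXA9.

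Interferon-response genes rose in HOXA9, 20 of 30 with 1 lower (20 and 1 adjusted over the list alone), with IFI27 (5.63-fold) and BST2 (4.64-fold). The camera test gave adjusted p = 0.049, and adjusted p = 0.52 with an estimated correlation. In TET1, 19 were higher and 3 lower (19 and 3 adjusted over the list alone), with no camera call (adjusted p = 0.22). Quantile normalization gave 17 interferon-response genes higher and 5 lower in HOXA9, and 15 and 6 in TET1. The equal array medians gave 16 higher and 9 lower in HOXA9, and 13 and 11 in TET1. Markers of other cell types moved in the same arrays. Of 14 haematopoietic markers, 13 rose in TET1 and 14 in HOXA9, with 0 lower (13 and 14 adjusted over the list alone), led by LYZ, lysozyme (3.3-fold and 3.86-fold). For this list camera gave adjusted p = 0.02 and 0.023, and adjusted p = 0.31 with an estimated correlation in each. After quantile normalization 7 rose and 2 fell in TET1, 9 rose and 3 fell in HOXA9, and the camera calls were lost. Under equal array medians 5 rose and 2 fell in each. Of 11 fibroblast markers, 9 rose and 1 fell in each group (9 and 1 adjusted over the list alone), with COL1A2 and COL3A1 at log2 1.79 and 1.3 in TET1. By camera the result was adjusted p = 0.039 in TET1 and 0.098 in HOXA9, and adjusted p = 0.45 in TET1 with an estimated correlation. Camera called 9 of 36 lists in each comparison, 0 of them with an estimated correlation.

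In all, limma called 14195 genes in TET1, 9931 higher (70%) and 4264 lower, and 13939 in HOXA9, 9957 higher (71.4%) and 3982 lower. At least 1.5-fold, 6499 and 5928 genes differed. After one quantile normalization 12137 were called in TET1 (49.5% higher) and 11748 in HOXA9 (46.7% higher), with 3904 and 3537 changed at least 1.5-fold, and with equal array medians 13510 (29.9% higher) and 13135 (28.4% higher). Of the calls in TET1 9705 and 8306 kept their direction under these scalings, and in HOXA9 9111 and 7716. Above the median level 59.2% of the calls in TET1 were higher.

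The shHMGA2 arrays were also set directly against the TET1 and the HOXA9 arrays. NETO2 was 38.4-fold and 41.9-fold higher in shHMGA2, IRS4 26.3-fold and 27.1-fold, INA 24.5-fold and 23.9-fold, and H2BC7 19.9-fold and 20.9-fold. All of these were against levels below the lower quartile of the TET1 and HOXA9 arrays (6.24). CA2 was 16.6-fold higher than in TET1, and HOXD10 was higher than in HOXA9 by 4.17 on the log2 scale. S100A4 was 19.6-fold and 20.5-fold lower, CD96 19.3-fold and 25.1-fold, and AGR2 14.7-fold and 26.5-fold, with CD96 and AGR2 below the 30th percentile in shHMGA2 (5.56 and 5.68). CST1, a cystatin, and MUC15, a mucin, were lower than in TET1 (log2 -4.14 and -3.9), and TMPRSS15 and SLC14A1 lower than in HOXA9 (log2 -4.96 and -4.39). Limma called 14752 genes against TET1, 31% of them higher in shHMGA2, and 14516 against HOXA9, 29.8% higher. After quantile normalization 47.1% and 49.1% were higher, and with equal array medians 63.6% and 65.2%.

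Genes called in more than one comparison with control bear on whether the 3 regulators share targets, but cannot settle it. The TET1 and HOXA9 comparisons cross the array sets, and RNA of another cell line was not excluded for the shHMGA2 rises. EPHA7, an ephrin receptor, rose 8.92-fold in shHMGA2, 3.41-fold in TET1 and 3.93-fold in HOXA9, and SERPINF1, an antiangiogenic serpin, 2.65-fold, 6.47-fold and 5.99-fold. GPM6B, DNM1P46, GJC1 (4.78-fold, 2.54-fold and 2.56-fold) and FKBP10 (4.84-fold, 2.13-fold and 2.92-fold) also rose in all 3. CCL2 (log2 -2.21, -2.79 and -2.92), ABCG2, a drug efflux transporter (log2 -1.66, -2.34 and -2.22), and SLAMF7 (log2 -1.52, -1.96 and -2.35) fell in all 3. So did AK5 (log2 -2.36, -2.16 and -1.12), BMP4 (log2 -1.45, -1.59 and -1.64) and RFPL4A (log2 -1.42, -2.41 and -2.47). All 3 comparisons use the same control arrays, so a high control value alone can give a fall in all 3. Among these genes the control SD was 0.08 for BMP4, 0.42 for CCL2 and 1 for RFPL4A. MAL2 fell in shHMGA2 and TET1 (log2 -1.83 and -2.56) and did not pass in HOXA9 (log2 0.14, adjusted p = 0.28).

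Of 3438 genes called in both shHMGA2 and TET1, 951 were higher in both, 775 lower in both and 1712 moved apart, against 1354, 538 and 1834 for independent lists. For shHMGA2 and HOXA9, 3425 genes were called in both, 1003 higher, 752 lower and 1670 apart, against 1358, 502 and 1799. Across genes, which are not independent replicates, fold changes of shHMGA2 correlated with those of TET1 at r = -0.01 and with those of HOXA9 at r = 0, against 0.45 in 100 simulations of unchanged groups that share the control arrays. In those simulations the fold changes hold noise alone, so the simulated r is not the level to expect where many genes changed. The covariance does not depend on the spread of the fold changes in this way. It was -0.00102 with TET1 and -0.000404 with HOXA9, against a simulated 0.0031. TET1 and HOXA9 had 13117 genes called in both, 9386 higher, 3728 lower and 3 apart, against 5369, 922 and 4453 for independent lists. Their fold changes correlated at r = 0.97, against a simulated 0.4, with a covariance of 0.329 against 0.0031. The 3 control arrays cannot be split so that each part keeps 2 arrays, and part of any excess may come from the shared controls. For TET1 and HOXA9 the covariance lay far above its simulated value, so the shared controls account for little of it. Their shared array set, subline number, serum and selection cannot be told apart from shared targets.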

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

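Of the tests in this part, the ratio of rises and the levels of AXL, CAV1 and CD44 were chosen after the results were seen. The split count and the MTAP test were written down before their results were known, though CDKN2A and KLHL9 had already been seen.

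Outside the genes tested, 61 of the 13837 probe sets with no single gene name were at least 2-fold higher in shHMGA2 than in control, and 14 at least 2-fold lower, a signal in data the comparisons did not use. Of these probe sets 1023 were called. No explanation for them was tested.

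Some genes low in control cells were higher in shHMGA2, among them IRS4, LIN28B (8.82-fold), INA, UCHL1 (7.53-fold) and, from the kidney cell list, HOXD10 and NEFM. RNA of another cell line is a candidate explanation: MTAP, a broadly expressed neighbour of CDKN2A in a stretch that MDA-MB-231 cells are known to lack, was at 6.28 in control and rose by 1.72, as that explanation needed. Of the 9 measured genes of the kidney cell list 1, NEFL, was above the median level in control (8.09, and 9.26 in shHMGA2). HOXD10 (5.95 and 10.42) stands in another list too, and CDH6, PAX2, LHX1 and TFAP2B did not pass. The labels name no sort, and IRS4, LIN28B, INA and UCHL1 were chosen after their values were seen. A rise of TET1 from HMGA2 depletion stays open beside RNA of another cell line. On the linear scale the TET1 rise was 1.62 times as large in replicate 3 as in replicate 1. That lies within the range of 0.96 to 2.26 for the 50 genes that rose at least 4-fold. The ratio cannot decide, since more RNA of another line and a stronger depletion in replicate 3 would each give it. The ELAC2 and HMGA2 probe set was also lowest in that replicate (8.47). Dilution of the cells' own RNA also stays open for falls under 2-fold. A 2-fold fall by dilution alone needs at least as much RNA of another line as of the cells' own. Control and shHMGA2 arrays correlated at 0.986 or above, and 65 of 18417 genes were at least 2-fold lower. These values argue against dilution alone for the 65 genes, though a share in their falls is not excluded. AXL, CAV1 and CD44 had a median change of -0.26 against -1.21 for the 65 genes, but the levels of the 3 genes in another line are not known here.

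Of the 10 splits of the control and shHMGA2 arrays into groups of 3, 1 gave as many called genes as the real 4834, which was the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 can be had.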

How the results depend on the processing

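Chosen after seeing the data were the fit of 10 arrays, which made the planned fit on all 12 columns an alternative, the list tests of TET1 against HOXA9 and the tolerance of 0.1 for correlations. Leaving out each array in turn gave 3626 to 4528 genes in shHMGA2 (710 to 1082 at 1.5-fold), 2.25 to 2.54 for TET1 and -0.86 to -0.59 for the ELAC2 and HMGA2 probe set, both called each time. Of the named genes' values over all settings, 63 in shHMGA2, 28 in TET1, 35 in HOXA9 and 61 in TET1 against HOXA9 kept their direction without a call, and 1716, 2002, 1970 and 238 kept both. Correlations of fold changes stayed within 0.1 of their values (-0.04 to 0.03, -0.03 to 0.03 and 0.95 to 0.97). One quantile normalization gave 3904 (TET1) and 3537 (HOXA9) genes at 1.5-fold, 145 genes between TET1 and HOXA9, and TET1 at -0.06 and 0.2. CBX7 and SNAI1 in TET1 turned to -0.07 and -0.02, neither called. Equal array medians gave TET1 at 0.04 and 0.28, and turned CBX7 in TET1 to -0.13 and PHC2 in HOXA9 to -0.2, neither called. These last turns follow from the scaling, which shifts all genes alike (the median gene from 0.25 to -0.22 and -0.21). The cause of the turns under quantile normalization was not tested. TET1 against HOXA9 had 1112 genes with all 12 columns, where the averaged columns shrink the spread, 142 in a fit of these groups only, and 11 to 72 without 1 array. TET1 in the arrays labelled TET1 ran from 0.41 to 0.6, its call lost at 0.41 without TET1 replicate 1. Testing all probe sets, more features, called 24412 (11844 at 1.5-fold) in TET1, 23847 (10862) in HOXA9, and 25245 and 24639 in shHMGA2 against TET1 and HOXA9. With an estimated correlation camera called 0 lists in shHMGA2, 0 in TET1, 0 in HOXA9 and 0 in TET1 against HOXA9, and fry called 26, 34, 34 and 2. Replicate numbers did not clearly pair the arrays. Between control and shHMGA2, same-number deviations correlated at 0.12, 0.13 and 0.01, and those of unlike numbers at -0.15 to 0.03. Replicate 3 of shHMGA2 correlated best with control replicate 2, and a weak pairing is not excluded. Between TET1 and HOXA9 the same-number value was 0.15. With 2 arrays per group deviations mirror each other, so this is a single value that cannot decide. With the number as a block 4890, 14094, 13806 and 69 genes were called in shHMGA2, TET1, HOXA9 and TET1 against HOXA9. Low signal over background limits dim genes, where the array sets differ most.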

Other observations

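The list tests of TET1 against HOXA9, the overlap of contrasts that share no array and all tests of explanations in this part were chosen after the results were seen.

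Several further gene groups held large changes in shHMGA2 without a camera call. In the same arrays 5 of 9 genes of the kidney cell list, MTAP and CDKN2A rose. RNA of another cell line was not excluded as a source of the rises in these groups, such as those of LIN28B and CDH2. Among 16 genes of the let-7 and oncofetal list, 5 rose and 4 fell (5 and 5 adjusted over the list alone), with IGF2BP1 and LIN28B, a repressor of let-7 maturation (8.82-fold), against SPRED1 (log2 -0.56), and camera gave adjusted p = 0.21. Of 27 Wnt and Notch genes 3 rose and 5 fell (4 and 6 adjusted over the list alone), with camera adjusted p = 0.97. HEY1, a Notch target, rose 9.47-fold, while of the Notch ligands JAG1 fell (log2 -0.83) and JAG2 rose (log2 0.33). Of 27 NF-kB targets and cytokines 2 rose, the interleukins IL1A (3.61-fold) and IL1B (2.4-fold), and 10 fell, with CCL2 and IL6 (log2 -0.81), with 2 and 10 adjusted over the list alone and camera adjusted p = 0.06. The class II genes HLA-DPA1 (3.72-fold) and HLA-DPB1 rose while the class I processing genes PSMB9 and TAP1 fell (log2 -0.66 and -0.59), as part of 14 antigen presentation genes with 3 higher and 7 lower (3 and 8 adjusted over the list alone) and camera adjusted p = 0.15. Of 23 mesenchymal genes 4 rose, with CDH2, N-cadherin (6.96-fold), and 9 fell, with CDH11 and S100A4 (2.27-fold), with 4 and 11 adjusted over the list alone and camera adjusted p = 0.12. Of 63 histone genes 9 rose, with H2BC7 and H4C5 (8.83-fold), and 5 fell, with H2BC1 (log2 -1.09), with 9 and 5 adjusted over the list alone and camera adjusted p = 0.21. SQLE, a rate-limiting enzyme of cholesterol synthesis, rose 2.05-fold, and PHGDH, the first enzyme of serine synthesis, 1.85-fold.

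Among DNA methylation enzymes, the methyltransferases DNMT1 and DNMT3B were lower than control in TET1 (log2 -0.8 and -0.91) and in HOXA9 (log2 -0.64 and -0.8), and DNMT3L and UHRF2 higher (log2 0.92 and 0.82 in TET1, 0.97 and 0.77 in HOXA9). None of these genes differed between TET1 and HOXA9. Of 21 such genes 7 were higher and 8 lower in TET1 (7 and 8 adjusted over the list alone), and 8 and 8 in HOXA9 (8 and 8 adjusted over the list alone), with camera adjusted p = 0.13 and 0.17. Quantile normalization gave 7 higher and 12 lower in each group. With equal array medians 3 were higher and 14 lower in TET1, and 3 and 13 in HOXA9. FOS and JUNB, subunits of AP-1, were 6.05-fold and 2.8-fold higher than control in TET1 and 4-fold and 2.17-fold in HOXA9. Of 26 immediate early genes 19 were higher and 3 lower in TET1 (19 and 3 adjusted over the list alone), and 20 and 4 in HOXA9 (20 and 4 adjusted over the list alone), with camera adjusted p = 0.085 and 0.23. Under quantile normalization 18 of these were higher and 2 lower in TET1, and 16 and 4 in HOXA9. Under equal array medians 13 were higher and 8 lower in TET1, and 8 and 7 in HOXA9. COX6C and COX7B, cytochrome oxidase subunits, were 3.82-fold and 3.86-fold higher in TET1 and 4.9-fold and 4.22-fold in HOXA9. Of 29 oxidative phosphorylation genes 14 were higher and 9 lower in TET1 (14 and 9 adjusted over the list alone), and 14 and 8 in HOXA9 (14 and 8 adjusted over the list alone), with camera adjusted p = 0.64 and 0.95. Under quantile normalization 16 of them were higher and 8 lower in TET1, and 15 and 8 in HOXA9. Under equal array medians, which move all genes of these arrays down alike, 6 were higher and 19 lower in TET1, and 6 and 18 in HOXA9.

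The TET1 and HOXA9 arrays differed from control in 14195 and 13939 genes, far more than from each other. Of the 14195 TET1 calls 9705 kept their direction after one quantile normalization of all arrays. Unlike distributions of the array sets are thus not the whole account. That step acts on summarised values and cannot remove offsets of single genes from a separate summary of the probes in each set. Separate normalization therefore stays open. A batch of arrays or RNA, another parent subline, as the source names have it, and a shared effect of the induced lines, which also differed in serum and selection, cannot be told apart, since each predicts few genes between TET1 and HOXA9 (80 were called) and a high correlation of their fold changes (r = 0.97). No sample of either group was in the other array set. A biological effect of the constructs stays among the open explanations.

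The TET1 transcript was not higher in the arrays labelled TET1 than in those labelled HOXA9. If labels had been exchanged, TET1 would be at least 2-fold higher in the arrays labelled HOXA9, and the upper 95% bound of that difference was 0.56 on the log2 scale. That test is void if the probe set does not see the introduced copy. Such a copy outside the measured transcript is itself a possible explanation, as the upper bound of TET1 minus HOXA9 was 0.1, and the labels give neither its species nor its part. The 2 explanations cannot be told apart here, and a construct that was not induced was not tested.

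The contrasts of shHMGA2 with control and of TET1 with HOXA9 share no array. Of the 80 genes called in the latter, 41 were also called in the former. Of these 28 were lower in both, against 7.4 for independent lists, 3 were higher in both, against 2.9, and 10 moved apart. Genes lower in both included SLC14A1 (log2 -1.04 in shHMGA2 and -2.81 in TET1 against HOXA9), TMPRSS15 (-1.28 and -2.04), AK5 (-2.36 and -1.03) and the microRNA precursors MIR221 (-0.56 and -1.64) and MIR21 (-0.55 and -1), named after their values were seen. Over all genes tested the fold changes of the contrasts had r = -0.01 and rho = -0.06, across genes that are not independent replicates.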
